A study of Homo sapiens with 4 samples.

How the data were processed

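LN229 cells were untreated or exposed to 5 µM ATO for 6 h, and total and polysomal RNA were each profiled on 1 array sample per condition. Per the labels' protocols, cells were lysed in a hypotonic buffer with cycloheximide, which holds ribosomes on mRNA, polysomes were separated on a sucrose gradient, and RNA of both fractions was purified with a Qiagen AllPrep kit. Single-stranded cDNA was made and biotin labelled with the Affymetrix GeneChip WT reagent kit, per the labels' protocols. Per the series' design text, each sample was run in technical triplicate, the data were pooled and the Transcriptome Analysis Console was used; how the pooling was done is not given in the sources used here, so a sample stands as a single value here. Per the submitters' processing notes, Affymetrix Expression Console was used; its version, the summary method, the normalization and the genome build are not given in the sources used here.

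The deposited values are on a log2 scale, to 2 decimals, and were used as given. They ran from 2.16 to 19.56, and 406 of 65528 probe sets exceeded 16 in at least 1 sample, so the scale includes a step beyond plain log2 intensity, and a fold on it need not be a fold of RNA. Medians over all probe sets were 4.22, 4.24, 4.26 and 4.25 in untreated polysomal, ATO polysomal, untreated total and ATO total RNA. With medians this close and the normalization unknown, an overall difference in the amount of polysomal RNA cannot be measured. Probe sets covered chromosomes 1 to 8 and 1722 probe sets of chromosome 9, as their identifiers show; other chromosomes were not analysed here. No detection calls were used. Every sample column was mapped to a sample.

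Probe sets were named through the platform annotation: 16127 had 1 gene symbol, 419 several and 48982 none in the table used here. Coding genes were those typed as protein coding in the RefSeq gene table of GRCh38.p14, matched through the Entrez identifier and used for gene type only; 7940 probe sets of 7749 genes qualified. No coordinates are given, since no build is named for the files. A gene was read from its probe set with the highest mean, and genes with a mean log2 value of at least 7.80 over the 4 samples, the median of coding genes, were kept, which left 3875.

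Groups were taken from sample titles; the source name of the ATO total sample reads polysomal and conflicts with its title. Differences of log2 values were formed for polysomal against total RNA in each treatment state, ATO against untreated in each fraction, and the difference of the polysomal/total ratio. With 1 sample per group no test was run, and genes past 1.5-fold, the threshold of the series' design text, were counted. Overlaps were set beside the number expected of independent lists (the product of the list sizes over the genes tested). The 35 gene lists fixed before the data were examined were described, where at least 5 members passed the filter (26 lists), by the percentile of their median among 10000 random lists drawn from 20 bins of mean level. These percentiles describe these samples and are no test of the treatment. Named genes followed a rule fixed before the data were examined. It took up to 12 coding genes per direction with the largest smaller difference among those of the same sign in both states (polysomal against total) or both fractions (ATO against untreated), and up to 10 per direction by the size of the ratio difference. PARM1 tied with PGM2 for the last place. It also took up to 4 members of each list, and any member of the NRF2, metal-response, heat shock and ATF4 lists. Lists with fewer than 5 members past the filter were not scored. These were the metal-response list (SLC30A1 alone), the BCL2 family (3 members), interferon-stimulated genes (2), the neuron marker list (GAD1 alone), the blood and epithelial marker lists (0 each) and 3 lists, of the mitochondrial genome, nuclear long noncoding RNAs and snoRNA host genes, of which 0 members were measured.

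Alternatives fixed before the data were examined were centring each sample on its median, quantile normalization, no filter, a filter at the 75th percentile, an offset of 32 added on the linear scale, a 2-fold threshold, the mean over a gene's probe sets, all named genes in place of coding genes, and subtraction of a loess trend (span 0.3) on mean level. A 1.25-fold threshold, counts without replication histones, and the noncoding RNA classes were added after the data were seen. The steps were tested on simulated data made from the mean level of 3875 genes over the 4 samples, with the same level in each simulated sample. Of 50 genes simulated at 1.5-fold, 54.0% passed the threshold, and all did at 2-, 3- and 4-fold. These shares were largely fixed by the settings, since 1.5-fold is the threshold itself and the larger folds lie well beyond the simulated noise. They check the arithmetic and do not measure how well true changes are found. Of 3675 unchanged genes 1 passed, and 7.0% of 200 unchanged lists lay outside the central 95%. Those lists all had the same size and were set against fewer random lists than the lists reported here. Every gene was given the same noise, set by the SD over genes of the total RNA difference (0.17). Among the 775 genes of lowest mean level that SD was 0.22 in total and 0.25 in polysomal RNA. The simulation can therefore understate false calls at low signal and in polysomal RNA. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and plots matplotlib 3.10.9.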

Results

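Array expression was measured in LN229, an established human glioblastoma cell line, untreated or treated with 5 µM ATO for 6 h. ATO is the usual abbreviation of arsenic trioxide, which the labels do not spell out. From each culture condition, total RNA and polysomal RNA (the RNA that sediments with mRNAs carrying several ribosomes) were profiled, giving 4 samples with 1 sample in each group. With no replicate, no difference below has a replicate error, a test or a p-value, and the number of arrays limits the precision of every value. Differences are on the log2 scale of the deposited values, polysomal minus total or ATO minus untreated. That scale is not plain log2 intensity, since 406 probe sets exceeded 16, the log2 ceiling of a 16-bit scanner, and folds are folds on that scale. The table analysed here held 65528 probe sets, on chromosomes 1 to 8 and part of 9; genes elsewhere were not analysed here. Of 7749 coding genes, 3875 passed the filter on mean level. Median log2 values over those genes were 11.23 in untreated polysomal, 11.20 in ATO polysomal, 11.04 in untreated total and 11.03 in ATO total RNA. The ATO total sample was grouped by its title, while its source name calls it polysomal. Over all probe sets it correlated with untreated total RNA at r = 0.991 and with ATO polysomal RNA at r = 0.987. The small nuclear RNAs U1, U4atac and U5 and 7SK, which are not translated, differed from untreated total RNA by a median of 0.11 in that sample, whereas ATO polysomal RNA stood at -2.66 against it.

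The comparison of polysomal with total RNA asked which transcripts were over- or under-represented on polysomes in each treatment state. Replication-dependent histone genes were among those standing highest, and YBX1 and the lamin genes among those standing lowest, in untreated and ATO cells alike. YBX1 (Entrez gene 4904, chromosome 1), an mRNA-binding cold shock domain protein, was 3.41-fold lower in polysomal RNA in untreated and 3.12-fold lower in ATO cells. H2AC8, a histone H2A gene on chromosome 6, was 2.75-fold and 2.43-fold higher. Other histone genes among those ranked highest were H4C5 (1.42 untreated, 1.19 ATO), H2BC14 (1.71, 1.10), H3C11 (1.18, 1.08) and H2AC4 (1.07, 1.49). Beside them ranked IFI6, an interferon-inducible gene (1.42, 1.25), SCRG1 (1.31, 1.22), WRAP73 (1.31, 1.22), PITHD1 (1.14, 1.23) and the ribonuclease P subunit RPP21 (1.16, 1.21). FIS1, a mitochondrial fission protein (1.10, 1.24), and MANF, a secreted endoplasmic reticulum stress protein (1.09, 1.05), completed that group. On the low side were the nuclear lamina genes LMNA (-1.43, -1.20) and LMNB1 (-1.43, -1.09), the poly(A)-binding protein PABPC4 (-1.19, -1.18) and the spliceosomal helicase SNRNP200 (-1.07, -1.43). They were joined by the chromatin regulators SAP130 (-1.41, -1.42) and KANSL1L (-1.50, -1.33) and the actin-nucleating complex subunit ARPC1A (-1.36, -1.36). PALS2 (-1.17, -1.61), the tissue plasminogen activator gene PLAT (-1.40, -1.10), DTL (-1.08, -1.35) and UBE2D4 (-1.02, -1.13) made up the rest. In all, 629 genes were over 1.5-fold higher and 183 over 1.5-fold lower in untreated cells, and 570 and 152 in ATO cells. Over 2-fold, the numbers were 58 and 26 in untreated and 50 and 20 in ATO cells. The median of all 3875 genes was 0.19 in untreated and 0.17 in ATO cells, and the split into higher and lower depended on that shift. With each sample centred on its median, 234 were higher and 383 lower in untreated cells, and 243 and 314 in ATO cells. Subtracting a loess trend on mean level gave 251 and 361, and 222 and 319.

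**Figure D1:**
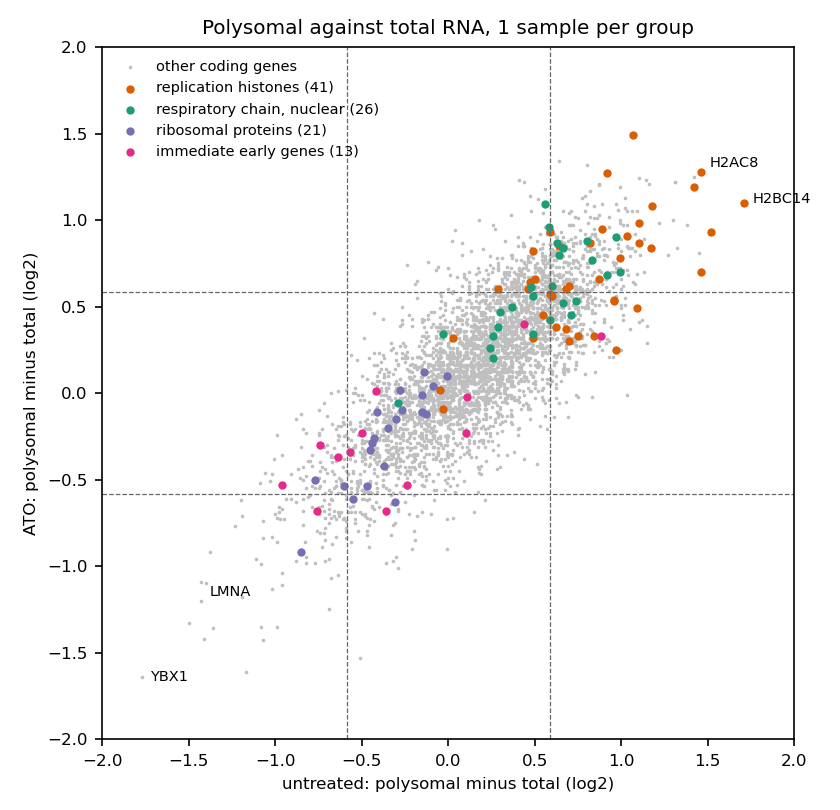
Polysomal minus total log2 difference of each of 3875 coding genes in untreated (x axis) and ATO treated (y axis) LN229 cells, 1 sample per group, with dashed lines at 1.5-fold and 4 gene lists in colour. Replication histones and respiratory chain genes lie toward the upper right and ribosomal protein and immediate early genes toward the lower left, and r across genes was 0.79.

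Gene lists fixed before the data were examined were described by the median of their members and its percentile among 10000 random lists of the same size matched on mean level. Lists with at least 5 members past the filter numbered 26, where 1.3 outside the central 95% would be expected of genes drawn at random. In untreated cells 11 lists lay outside that range, and 10 in ATO cells. Of these, 2 lists lay above and 7 below in both states. The 41 replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, had medians of 0.82 and 0.64, which is 0.63 and 0.47 relative to all genes. Of them, 31 and 25 were over 1.5-fold higher and none was over 1.5-fold lower. H2BC14 and H2BC12 (1.52, 0.93) stood highest in untreated cells, H4C8 was near 0 (-0.05, 0.02), and near-identical histone copies can share probes. The 26 nuclear genes of the mitochondrial respiratory chain and ATP synthase had medians of 0.58 and 0.55, or 0.40 and 0.38 relative to all genes. Of those, 13 and 12 were over 1.5-fold higher, among them NDUFA2 (0.99, 0.70), NDUFS6 (0.97, 0.90) and COX5B (0.80, 0.88), while SDHA stood at -0.29 and -0.06. Both lists exceeded all of the random lists in both states.

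Ribosomal protein mRNAs, the main class with a terminal oligopyrimidine (TOP) start that ties translation to mTOR, stood low, with medians of -0.35 and -0.20 over 21 genes (-0.54 and -0.37 relative to all genes). All 21 were below 0 in untreated and 17 in ATO cells, and 3 in each state were over 1.5-fold lower, among them RPS12 (-0.85, -0.92). The other 5 TOP mRNAs had medians of -0.55 and -0.35, with EEF1D (-0.82, -0.55) and EIF3H (-0.76, -0.68) lowest and BTF3 near 0 (0.10, 0.01). Immediate early genes, the early transcriptional targets of growth factor signalling, had medians of -0.42 and -0.30 over 13 genes, with EGR1 (-0.96, -0.53) and MYC (-0.76, -0.68) low and SRF (0.88, 0.33) high. The 5 glycolysis and hypoxia genes had medians of -0.51 and -0.47, including the glucose transporter SLC2A1 (-1.07, -0.74) and hexokinase HK2 (-0.84, -0.50), with 4 of 5 below 0 in each state and PDK1 above it (0.32, 0.23). Extracellular matrix genes had medians of -0.30 and -0.24 over 11 genes, with the fibronectin gene FN1 at -0.74 and -0.54 and THBS2 at -0.62 and -0.69. Mitosis genes (14 genes, -0.24 and -0.20) and DNA replication genes (11 genes, -0.22 and -0.16) also lay below the random lists. In untreated cells the mitosis median came within the random range with the filter at the 75th percentile (-0.12, percentile 6.54). The other TOP mRNAs did so in ATO cells with all named genes (percentile 2.97). Within the mitosis list, KIF20A (-1.20, -0.62) was low and PTTG1 (0.96, 0.54) high.

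A further 3 lists lay below the random lists in 1 state: eIF4E-sensitive mRNAs in untreated cells (-0.29, against 0.01 in ATO cells), heat shock genes in ATO cells (-0.10, against -0.11 in untreated cells) and zinc finger genes in untreated cells (0.02, against 0.09). The heat shock call in ATO cells ended with no filter (percentile 3.105), with all named genes (5.0) and after the loess subtraction (2.765). The zinc finger median became -0.17 with centred samples. Its call ended with the filter at the 75th percentile (percentile 4.485), the mean over probe sets (2.535) and all named genes (6.985). The remaining lists stayed within the random range in both states. Their medians in untreated and ATO cells were 0.41 and 0.29 for inflammatory genes, 0.35 and 0.50 for endoplasmic reticulum chaperones, 0.33 and 0.17 for cholesterol synthesis, and 0.30 and 0.24 for mRNAs with upstream open reading frames. Translation initiation factors had 0.28 and 0.24, autophagy genes 0.28 and 0.17, integrins and receptors 0.27 and 0.08, and p53 targets 0.21 and 0.51. ATF4 targets had 0.19 and 0.12, the proteasome 0.09 and 0.31, glioma stem and lineage genes 0.09 and 0.05, NRF2 targets -0.03 and 0.29, DNA repair genes -0.05 and -0.01, and tRNA synthetases -0.08 and -0.11.

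**Figure D2:**
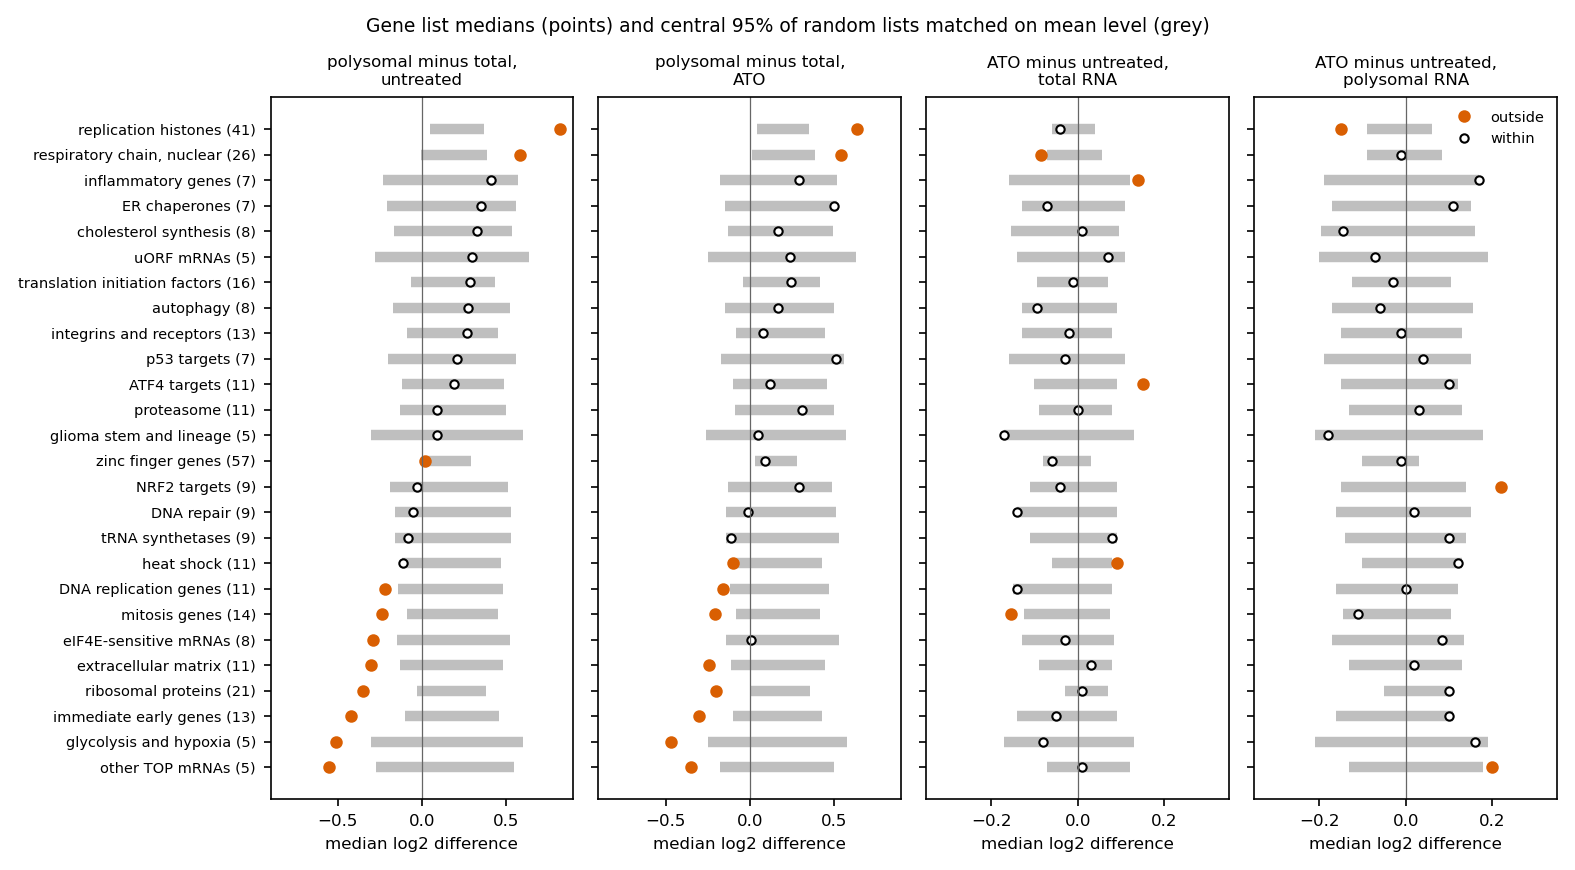
Median log2 difference of each of 26 gene lists (points; number of genes in parentheses) in 4 comparisons, with the central 95% of random lists of the same size and mean level in grey. Filled orange points lie outside that range; the x axes of the 2 ATO panels are narrower than those of the polysomal panels.

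The series' own comparison set the polysome-enriched lists of untreated and ATO cells side by side, to find transcripts enriched on polysomes in 1 state. Most of the ordering was shared. Across the 3875 genes, which are not independent replicates, the differences in the 2 states correlated at r = 0.79 (Spearman's rho 0.78), and 81.8% of genes had the same sign. Genes over 1.5-fold higher in polysomal RNA in both states numbered 327, where 92.5 would be expected of independent lists, while 302 passed in untreated cells alone and 243 in ATO cells alone. For lower genes the numbers were 91 in both (7.18 expected), 92 in untreated cells alone and 61 in ATO cells alone. No gene passed 1.5-fold in opposite directions. The balance of higher and lower shared genes turned with the scaling: 105 were higher and 206 lower in both states with centred samples, and 100 and 209 after the loess subtraction. Of the 243 genes that passed in ATO cells alone, 235 were also above 0 in untreated cells and 26 had a ratio that differed over 1.5-fold between the states. Of the 302 that passed in untreated cells alone, 293 were above 0 in ATO cells and 31 differed over 1.5-fold.

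ATO was next compared with untreated cells in total RNA, which gives RNA abundance. Differences were small: 4 coding genes were over 1.5-fold higher, 14 over 1.5-fold lower and none reached 2-fold. The 4 higher genes, named after their values were seen, were CCDC149 (0.64), TAF1A and TRAIP (0.61 each) and LRRC8C (0.59). CEP85L (-0.76) and TRNAU1AP, a protein of selenocysteine tRNA biology (-0.74), were lowest. Of 26 lists, 5 lay outside the random range, where 1.3 would be expected of genes drawn at random. That number does not measure chance between samples. Genes of a list can vary together, and some lists share members, which can put more lists outside without an effect of ATO. ATF4 targets, the amino acid synthesis and stress genes of the integrated stress response, had a median of 0.15 (percentile 99.96 of random lists), with 8 of 11 genes above 0 and none past 1.5-fold. The serine synthesis genes PSAT1 and PSPH (0.25 each) and PHGDH (0.21) and the cystine transporter SLC7A11 (0.24) led that list, followed by VLDLR (0.17), MTHFD2 (0.15), ASNS (0.10) and SESN2 (0.10). STC2 (-0.09), GADD45A (-0.06) and ATF3 (-0.05) were below 0. Heat shock genes had a median of 0.09 (percentile 98.4), with 10 of 11 above 0 and none past 1.5-fold. HSPB1 (0.22), CACYBP (0.19), HSPA4L (0.19), DNAJA1 (0.18) and DNAJB4 (0.11) were followed by HSPA4 and HSPE1 (0.09 each), HSPD1 and HSP90AB1 (0.08 each) and DNAJB6 (0.01), while HSPA6 was at -0.05. Inflammatory genes had a median of 0.14 (percentile 98.5) over 7 genes, with PTGS2 at 0.35 and TNFAIP3 at 0.31; without the filter, which adds dim genes, the median became -0.035. Mitosis genes (-0.16, percentile 0.595) and respiratory chain genes (-0.08, percentile 0.785) lay below the random lists. Of the mitosis genes 11 of 14 were below 0, with HMMR at -0.48 and CENPF at 0.32, and of the respiratory chain genes 17 of 26, with CYC1 at -0.38 and COX6C at 0.27. ATF4 targets and respiratory chain genes stayed outside the random range under all 8 alternative settings. All of these settings reuse the same samples, and centring shifts a list and its random lists alike, so it could hardly end a call. Heat shock genes (median equal to the upper limit of 0.09 with the filter at the 75th percentile and with all named genes), inflammatory genes (93.8 after the loess subtraction) and mitosis genes (7.59 with the filter at the 75th percentile) each lost that place under at least 1 setting. NRF2 targets, here 9 antioxidant and related genes on the chromosomes analysed, had a median of -0.04 in total RNA. NRF2 targets on other chromosomes were not analysed here, so this median does not speak for the whole response. SLC30A1, a zinc exporter and the 1 measured member of the metal-response list, stood at 0.33 in total and 0.27 in polysomal RNA.

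In polysomal RNA, 10 coding genes were over 1.5-fold higher with ATO and 34 over 1.5-fold lower, which became 16 and 27 with centred samples and 15 and 26 after the loess subtraction. POP7, a subunit of ribonuclease P and ribonuclease MRP, was 2.16-fold lower (-1.11) and alone passed 2-fold. PKIA (-0.99) and SLC39A8, a zinc and manganese importer (-0.94), came next, and SIMC1 (0.73) and CYP2J2 (0.72) were highest; these 4 were named after their values were seen. Of 26 lists, 3 lay outside the random range, where 1.3 would be expected of genes drawn at random. NRF2 targets had a median of 0.22 (percentile 99.9), with 8 of 9 genes above 0 and none past 1.5-fold. Malic enzyme ME1 was at 0.58, the autophagy receptor SQSTM1 at 0.34, SLC7A11 at 0.28, the glutathione synthesis subunit GCLM at 0.24 and the peroxiredoxin PRDX1 at 0.22. TKT (0.09), PGD (0.07) and GCLC (0.01) were near 0, and GSR was at -0.10. Replication histones had a median of -0.15 (percentile 0.035), with 33 of 41 below 0 and H2BC3 (-0.67) and H2BC12 (-0.63) over 1.5-fold lower. The other TOP mRNAs had a median of 0.20 (percentile 98.3), led by EEF1D (0.28), but came within the random range with quantile normalization (percentile 89.0) and after the loess subtraction (94.9). Against random lists matched on the untreated polysomal/total ratio as well, a check chosen after the data were seen, the histones moved to percentile 29.1 and the other TOP mRNAs to 92.0, both within the random range, and NRF2 targets stayed at 99.4. ATF4 targets had 0.10 and heat shock genes 0.12, both within the random range. Apart from the histones, no list named for either ATO comparison above had a member past 1.5-fold in that comparison.

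**Figure D3:**
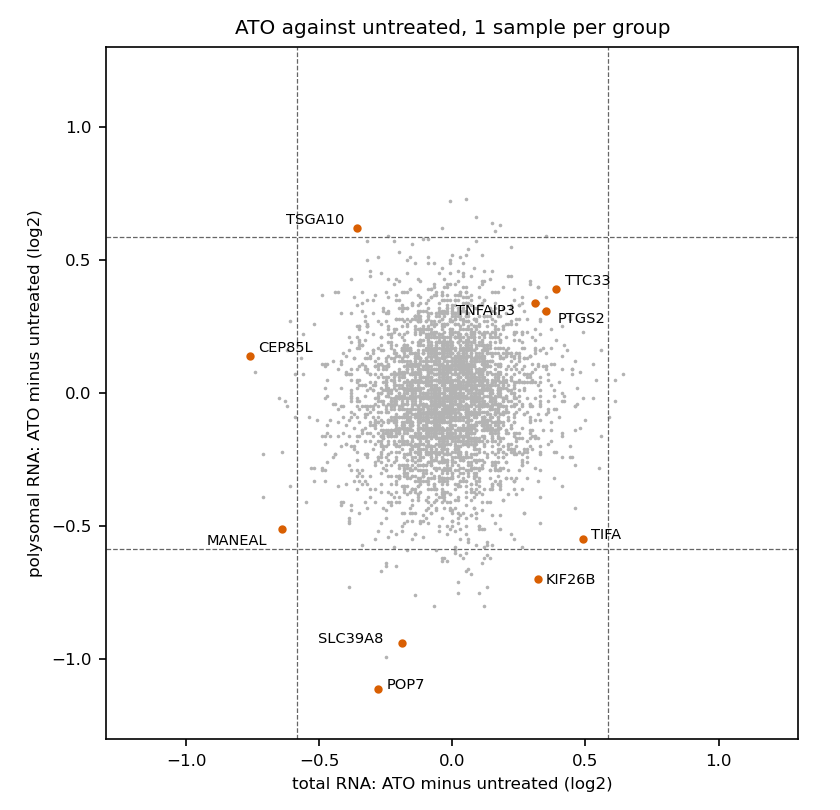
ATO minus untreated log2 difference of each of 3875 coding genes in total (x axis) and polysomal RNA (y axis), 1 sample per group, with dashed lines at 1.5-fold and 10 genes named. The cloud is round (r across genes 0.05), and no gene lies past 1.5-fold in both fractions.

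The ATO differences in total and polysomal RNA, which share no sample, were then set against each other. Across genes they correlated at r = 0.05, and at r = 0.03 among the 775 genes of highest mean level, with 51.1% of all genes sharing a sign. No gene passed 1.5-fold in both fractions. At 1.25-fold, a threshold chosen after the data were seen, 3 genes were higher in both (4.40 expected of independent lists), 25 lower in both (14.5 expected) and 14 opposite (16 expected). Genes highest with ATO in both fractions were TTC33 (0.39 total, 0.39 polysomal), ATP6V1E2 (0.35, 0.59), CFAP36 (0.35, 0.36), OTUD3 (0.44, 0.29), AIDA (0.32, 0.40), LRAT (0.32, 0.40) and GCC1 (0.32, 0.34). PTGS2, the inducible cyclooxygenase (0.35, 0.31), TNFAIP3, an inhibitor of NF-kB signalling (0.31, 0.34), FGF10 (0.34, 0.31), LAD1 (0.29, 0.41) and the mRNA capping enzyme RNGTT (0.29, 0.42) followed. Genes lowest in both were MANEAL (-0.64, -0.51), FIGNL1 (-0.55, -0.41), CEP162 (-0.71, -0.39), IFRD2 (-0.42, -0.42), the ATP synthase assembly factor ATPAF1 (-0.42, -0.41) and CARD19 (-0.41, -0.41). E2F5 (-0.39, -0.47), the ephrin receptor EPHA4 (-0.39, -0.49), FBXO45 (-0.39, -0.73), WRAP73 (-0.39, -0.48), cytochrome c1 CYC1 (-0.38, -0.44) and SCLY, selenocysteine lyase (-0.38, -0.42), made up the rest. Values below the filter level of 7.80 entered the differences of LRAT (7.64 in untreated polysomal), FGF10 (7.65 in untreated total) and CEP162 (7.62 in ATO polysomal, 7.77 in ATO total). The same held for EPHA4 (7.79 in ATO polysomal) and WRAP73 (7.73 in ATO total), and none of these sizes is firm.

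Finally, the polysomal/total ratio in ATO cells was set against that in untreated cells, to ask which transcripts differed in polysome association with ATO. In this comparison 62 coding genes were over 1.5-fold higher and 78 over 1.5-fold lower, or 78 and 63 with centred samples. The ratio difference takes in the error of all 4 samples. Its SD over genes was 0.27, against 0.17 for the ATO difference in total and 0.21 in polysomal RNA. More genes can therefore pass 1.5-fold here than in either fraction without an effect of ATO. With the values as given, 2 of the lower genes passed 2-fold. Those were TIFA, an adaptor of NF-kB signalling (ratio difference -1.04; 1.03 in untreated, -0.01 in ATO cells), and the kinesin gene KIF26B (-1.02; -0.51 in untreated, -1.53 in ATO cells). Below them came ACYP2 (-0.92), the chromatin remodeller CHD7 (-0.89), METTL6 (-0.86), CNPY4 (-0.85), the protocadherin PCDH7 (-0.84), DNER (-0.83), POP7 (-0.83) and the anaphase-promoting complex subunit ANAPC1 (-0.82). The highest were TSGA10 (0.98), CEP85L (0.90), ACY1 (0.89), the lysosomal channel TMEM175 (0.88), the mitochondrial nuclease EXOG (0.86) and ECI2, an enzyme of fatty acid oxidation (0.83). CCDC138, NOCT and TRNAU1AP (0.82 each) and PARM1 (0.81) followed. Of 26 lists, 2 lay outside, where 1.3 would be expected of genes drawn at random. Ribosomal proteins lay above the random lists (0.13, percentile 99.6, 16 of 21 above 0) and replication histones below them (-0.12, percentile 0.52, 28 of 41 below 0). Neither stayed outside when random lists were also matched on the untreated ratio (percentiles 73.6 and 56.8). The share of genes past 1.5-fold was 7.74% among the 775 genes of lowest mean level and 0.903% among the 775 of highest.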

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

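Each test in this part, the 1.25-fold size rule and the noncoding classes were chosen after the results they bear on were seen. Among the named genes, 9 differed in opposite directions by over 1.25-fold between treatment states or between fractions; with 1 sample on each side these differences were not tested. All 9 were named for the size of their ratio difference, a rule that favours opposite signs. In polysomal against total RNA, ACY1 stood at -0.43 in untreated and 0.46 in ATO cells (difference 0.89), ACYP2 at 0.51 and -0.41 (-0.92), ANAPC1 at 0.44 and -0.38 (-0.82) and PARM1 at -0.38 and 0.43 (0.81). In ATO against untreated cells, total RNA and polysomal RNA gave 0.33 and -0.49 for ANAPC1 (-0.82), 0.46 and -0.43 for CHD7 (-0.89), -0.49 and 0.37 for EXOG (0.86) and -0.44 and 0.38 for NOCT (0.82). The same comparison gave -0.38 and 0.43 for PARM1 (0.81), 0.49 and -0.55 for TIFA (-1.04) and -0.36 and 0.62 for TSGA10 (0.98). Values below the filter level entered the differences of ACYP2, CHD7 and TSGA10, so their sizes are not firm. Over all coding genes, 6 were opposite between treatment states at this size and 14 between fractions, where for the fractions 16 would be expected of independent lists.

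Genes whose polysomal/total ratio differed over 1.5-fold with ATO numbered 62 higher and 78 lower. Array noise that grows at low signal is a candidate explanation for much of this: the share past 1.5-fold was 8.57 times as high among the 775 genes of lowest mean level as among the 775 of highest (7.74% against 0.903%). Error of single probe sets cannot be told apart from gene-level differences, because in the 13 genes with a pair of probe sets past the filter their ratio differences correlated at r = 0.64 with a 95% interval of 0.14 to 0.88. Some of those pairs belong to families with similar copies, such as NBPF19 and GTF2H2, so they bear only weakly on single-copy genes. An effect of ATO on polysome association of single genes stays open and untested without replicates.

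Gene lists that lay outside random lists in polysomal RNA with ATO or in the ratio difference share the untreated samples with the polysomal/total ratio, so chance in an untreated sample may place a list low at baseline and high afterwards. With random lists matched on the untreated ratio as well as on mean level, 0 of the other 4 list medians stayed outside: ribosomal proteins moved to percentile 73.6 in the ratio difference, other TOP mRNAs to 92.0 in polysomal RNA, and replication histones to 29.1 in polysomal RNA and 56.8 in the ratio difference. For NRF2 targets in polysomal RNA this argues against such regression as the whole cause, since the list stayed at percentile 99.4. That matching uses the same untreated polysomal sample and can remove a true difference along with the chance one, so an effect of ATO on histone or TOP mRNAs stays open. For the NRF2 targets, a higher polysomal level with ATO is a hypothesis that 1 sample per group leaves untested. The ATO difference in total RNA also shares the untreated total sample with the untreated ratio. The lists outside the random range there, mitosis genes among them, were not matched in this way.

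Outside the coding genes, 808 named genes of other types passed the filter. With ATO, 9 of them were over 1.5-fold higher in total RNA (highest 0.72) and 21 in polysomal RNA (highest RMRP at 1.08, from log2 values of 5.09 and 6.17 that lie below the filter level and give no firm size), and 24 and 8 were lower. The 10 copies of 5S ribosomal RNA, which share 3 distinct sets of values, were all lower in ATO total RNA, from -0.94 to -0.59. In polysomal RNA the 3 sets differed by 0.05, -0.24 and -0.19. The 17 5S pseudogenes past the filter, whose probes may read the same RNA, had medians of -0.53 in total and 0.14 in polysomal RNA. Loss of small RNAs as a class from the ATO total sample is unlikely to be the cause, because 21 other small RNAs (spliceosomal, 7SK, small nucleolar, Cajal body and Y RNAs) had a median of 0.04 there, with quartiles of -0.08 and 0.14. Some small RNAs outside those 21 were as low there, namely RMRP (-1.02), RN7SL671P (-1.16), RNU2-30P (-0.79) and RNU1-138P (-0.70), while RNU6-1104P and RNU6-1304P were at 0.62. A difference peculiar to that array, a loss of 5S RNA with part of the other small RNAs and an effect of ATO all stay open.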

How the results depend on the processing

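No analysis paired by replicate was possible, because each group holds 1 sample and the labels number no replicates that could be paired. With 1 sample no replicate could be left out. This concerns pairs of replicates: a fit with the other factor (treatment or fraction) as the block, whose error would be the ratio difference itself, could be made and was not run. Of 216 counts recomputed under an alternative, 137 stayed within 1.5 times and 79 did not. Of 1015 list medians 1000 stayed the same, 11 moved and 4 changed sign. Of 855 values of named genes 1 moved. A change of filter leaves a gene's own value as it is, and the mean over probe sets can change only genes with several probe sets. Agreement of the named-gene values was therefore partly fixed in advance and is weak evidence of robustness. The list medians and calls share this limit. A change of filter alters a list median only through members added or dropped, and centring shifts a list and its random lists alike. Quantile normalization, the mean over probe sets and counts without replication histones (added after the data were seen) moved no count by over 1.5 times. All 9 lists outside the random lists in both states stayed outside after the loess subtraction. List calls that ended were, in total RNA with ATO, heat shock (75th percentile filter and all named genes, in each a tie with the upper limit), inflammatory (quantile, no filter, all named genes, loess; under 5 members at the 75th percentile filter) and mitosis genes (75th percentile filter); in polysomal RNA with ATO, other TOP mRNAs (quantile, loess). In polysomal against total RNA they were mitosis genes (75th percentile filter) and zinc finger genes (75th percentile filter, mean over probe sets, all named genes) in untreated cells, and heat shock (no filter, all named genes, loess) and other TOP mRNAs (all named genes) in ATO cells. DNA replication and glycolysis and hypoxia genes had under 5 members at the 75th percentile filter and were not scored there. Counts below are higher and lower. Centring, which takes the medians of 0.19 and 0.17 to 0, gave 234 and 383 for polysomal against total RNA in untreated and 243 and 314 in ATO cells, with 105 higher in both, 129 in untreated alone, 138 in ATO alone and 206 lower in both, and 16 higher with ATO in polysomal RNA. Loess gave 251 and 361 in untreated and 222 and 319 in ATO cells, with 100 higher in both, 151 in untreated alone, 122 in ATO alone and 209 lower in both. The zinc finger median in untreated cells (0.02) became -0.17 with centring, -0.13 with loess and -0.07 at the 75th percentile filter; the inflammatory median in total RNA with ATO (0.14) became -0.035 with no filter. The filter at the 75th percentile, which tests 1939 genes, gave 348 and 92 in untreated and 320 and 80 in ATO cells, with 200 higher in both, 148 in untreated alone, 120 in ATO alone and 54 lower in both. With ATO it gave 0 and 2 in total RNA, 4 and 4 in polysomal RNA and 11 and 12 in the ratio difference, and 2 lists (of 5) outside in total RNA. No filter, which tests 7749 genes, gave 473 higher in untreated alone and 412 in ATO alone, and with ATO 71 and 83 in total RNA, 64 and 115 in polysomal RNA, 305 and 311 in the ratio difference and 4 higher in both fractions. The offset of 32 gave 0 and 8 with ATO in total RNA. All named genes gave 374 lower in untreated, 334 lower in ATO cells and 251 lower in both, and with ATO 13 and 38 in total RNA, 31 higher in polysomal RNA, 110 higher in the ratio difference and 3 lists outside in total RNA. The 2-fold threshold gave 58 and 26 in untreated and 50 and 20 in ATO cells, with 16 higher in both, 42 in untreated alone, 34 in ATO alone and 12 lower in both; with ATO it gave 0 and 0 in total RNA, 0 and 1 in polysomal RNA and 0 and 2 in the ratio difference. The 1.25-fold threshold, chosen after the data were seen, gave 1418 and 505 in untreated and 1381 and 453 in ATO cells, with 1026 higher and 292 lower in both; with ATO it gave 101 and 184 in total RNA, 169 and 306 in polysomal RNA, 406 and 411 in the ratio difference, and 3 higher and 25 lower in both fractions. Thresholds, filters, centring and the gene set move counts by their construction; for the other values the cause was not tested. Low signal limits single genes: the SD over genes of the ratio difference was 0.33 among the 775 genes of lowest mean level and 0.21 among the 775 of highest.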

Other observations

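The noncoding classes described here were chosen after the data were seen; the test of the mitochondrial ribosomal proteins was chosen before its result was seen. Small nuclear, nucleolar and Y RNAs were far lower in polysomal than in total RNA, whereas the 25 microRNA loci past the filter had medians of -0.03 in untreated and -0.02 in ATO cells, with 1 over 2-fold lower in each state. The 13 U1, U4atac and U5 spliceosomal and 7SK RNAs past the filter, with 11 distinct sets of values, had medians of -2.51 in untreated and -2.66 in ATO cells, and all were over 2-fold lower in both. RNU4ATAC, of the minor spliceosome, was 16.6-fold and 13.6-fold lower, and RN7SK, which restrains transcription elongation, 5.74-fold and 4.69-fold lower. The 3 small nucleolar RNAs had medians of -2.63 and -2.75, and the 3 Y RNAs -2.26 and -2.46, with RNY1 32.9-fold and 23.4-fold lower. RMRP, the RNA of ribonuclease MRP, had log2 values of 11.49 and 10.47 in untreated and ATO total RNA, and polysomal values of 5.09 and 6.17 that lie below the filter level, so the size of its difference is not firm. The 10 copies of 5S ribosomal RNA, a component of the large ribosomal subunit, share 3 distinct sets of values. RNA5S11 and the copies identical to it stood at 0.28 in untreated and 0.92 in ATO cells. RNA5S10 and its identical copies stood at 0.76 and 1.15, and RNA5S9 at 0.72 and 1.47. With ATO, total RNA of these sets was lower by the -0.59, -0.63 and -0.94 left open above. Their polysomal RNA differed by 0.05, -0.24 and -0.19. The 85 long noncoding RNAs had medians of 0.24 and 0.23, close to the coding genes, and ranged from -1.23 to 1.21 in untreated cells. LUCAT1 stood at 0.97 and 0.78, LINC00339 at 0.77 and 0.93 and LINC00622 at -1.23 and -1.11.

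The high polysomal/total ratio of respiratory chain transcripts raised the hypothesis that transcripts of mitochondrial proteins share it. The 36 mitochondrial ribosomal protein genes, on no list fixed earlier, had a median of 0.43 in untreated cells (percentile 99.7 of random lists) and 0.43 in ATO cells (percentile 99.7), which is consistent with it. Of them, 11 and 12 were over 1.5-fold higher and 0 over 1.5-fold lower, with MRPS17 at 1.06 and 1.05 and MRPS27 at -0.46 and -0.20. With ATO their medians were -0.03 in total and -0.06 in polysomal RNA, within the random range. Short mRNAs are common to histone, respiratory chain and mitochondrial ribosomal genes and also to the low-ranking cytoplasmic ribosomal proteins, and mRNA length was not tested.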
